A study of Mus musculus with 92 samples.

How the data were processed

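The series holds liver RNA from CD-1 mice, an outbred stock, that received HFPO-DA by mouth every day. HFPO-DA (hexafluoropropylene oxide dimer acid) is a perfluoroalkyl ether carboxylic acid used in making fluoropolymers. Per the labels' protocols, the livers were fixed in formalin and embedded in paraffin, and thin sections scraped from slides were measured by TempO-Seq. In that targeted assay a pair of DNA oligonucleotides anneals to each chosen transcript, the pair is ligated, and the ligated probes are amplified and sequenced, so each value counts a probe and not reads along a transcript. The probe pairs carry no molecular identifiers that the labels mention, so confidence statements that rest on counts cover counting error only.

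The deposited table holds raw counts per probe, 1 column for each of the 92 animals. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.17.1.14 and aligned with Bowtie, whose version was not given in the sources used here. The genome build and the probe manifest were likewise not given, so no coordinates are printed. The table had 30146 probe rows for 21400 gene symbols, of which 6309 had more than 1 probe, and all of its columns matched a sample in the labels. Of the symbols, 21069 were in the reference table of mouse gene names. Counts of probes with the same symbol were summed to 1 value per gene. Probes of near-identical genes (Cyp4a10, Cyp4a31 and Cyp4a32; Acot1 and Acot2; Saa1 and Saa2; Cyp3a41a and Cyp3a41b) may take each other's transcripts, so values that set such genes apart are uncertain.

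Samples were grouped by sex, duration and dose as the labels state them, which gave 20 groups of 3 to 5 animals. Nothing in the labels gives a batch, a litter or a pairing, and replicate numbers only name the animals. Duration went together with age and with sequencing depth, so a difference between 9 and 18 months cannot be assigned to any one of them. Library totals ran from 403108 to 17638156 counts.

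Counts-per-million values (CPM) were computed with TMM-normalised library sizes in edgeR 4.0.16, run in R 4.3.3, and are given as mean ± SD over the animals of a group. Genes were filtered with filterByExpr and tested with edgeR's quasi-likelihood F test with robust estimation. Adjusted p-values are Benjamini-Hochberg values within a comparison, and a gene was called changed at an adjusted p under 0.05. Each of the 16 comparisons of a dose with 0 mg/kg came from a fit of the 5 dose groups of 1 sex and duration. Differences between sexes or durations in the response to 5 or 0.5 mg/kg were tested as interaction terms in 1 fit of all 92 samples and 13681 genes, as were 4 comparisons among the control groups. Log2 fold changes are those of the fit, with SE computed as the fold change divided by the square root of F. The common biological coefficient of variation of the fit of all samples was 0.551.

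Before the data were examined, 29 gene lists, the rule for genes to be named, the tests and nearly all alternatives were fixed. The lists cover fatty acid and sterol metabolism, nuclear receptor targets, stress, cell cycle, acute phase proteins, amino acid and glucose metabolism, sex-biased and zonal hepatocyte genes, and markers of other cell types. Of their genes, 9 had no probe. Lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, two-sided, adjusted over the lists of a comparison. The alternatives for lists were camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance without comparing them with other genes. Lists with fewer than 3 genes tested had no list test. A score for fatty acid oxidation was the mean, over the genes of the peroxisomal, mitochondrial and microsomal oxidation lists, of log2(CPM + 1) minus the mean of the controls of the same sex and duration. It was compared with the controls by a two-sided exact permutation test.

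The named genes are those with a mean of at least 10 raw counts per library and the largest called changes. They were the 8 rises and 8 falls at 5 mg/kg, 5 and 5 at 0.5 mg/kg, 3 and 3 at 0.1 and 0.05 mg/kg, and 4 and 4 in interactions and control comparisons, where interactions needed the count minimum in 1 group only. They also include up to 4 members of each list with the smallest adjusted p at 5 mg/kg. Added to these were Cyp4a10, Cyp4a14, Acot1, Ehhadh, Pdk4, Pex11a, Fgf21, Cyp2b10, Cyp1a2, Cyp3a11 and Ppara throughout. Some genes within these rules are not reported here. Any other gene is said to have been chosen after its values were seen.

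The alternatives tried were RLE normalisation, no low-count filter, a fit of only the 2 groups compared, a fit of all 92 samples, DESeq2 1.42.0, and probes tested without summing. Stricter thresholds were an adjusted p under 0.01 and a fold of at least 1.5. Each library was left out in turn, and the 1 library below 0.333 of the median total of all libraries was left out. An alternative chosen after seeing the data left out male 9-month 5 mg/kg replicates 4 and 5. The list tests of 18-month females at 5 and 0.5 mg/kg without the low-total library were also chosen after seeing the data.

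The tests were tried on simulated counts drawn from the samples' own means and library sizes. In the simulation of 5 mg/kg in 9-month males, with 11123 genes tested, edgeR recovered 40 of 100 genes changed 2-fold and 72 of 100 changed 4-fold, and called 7 unchanged genes. In that of 18-month males, with 12652 genes, it recovered 3 and 40 of 100 and called 3 unchanged genes. In that of the sex difference at 5 mg/kg and 9 months, with 13174 genes, it recovered 4 and 40 of 100 and called 1 unchanged gene. DESeq2 recovered 46 and 69 in the 9-month males with 19 unchanged genes called, and 7 and 54 in the 18-month males with 21. A simulated list of 20 raised genes was called by each of the 3 list tests, and 0 of 28 unchanged lists were. Each gene was drawn independently, so the list tests were not tried on genes that move together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.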

Results

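Livers of 92 CD-1 mice were measured, 1 library for each animal. Males and females received HFPO-DA daily by gavage for 9 or 18 months, at 5, 0.5, 0.1 or 0.05 mg/kg, or 0 mg/kg as controls. In rising order of dose, the male groups held 4, 5, 5, 5 and 5 animals at 9 months and 5, 4, 3, 5 and 3 at 18 months. The female groups held 5, 4, 5, 5 and 5 animals at either duration. Total counts ran from 4443349 to 7717469 at 9 months and, without 1 library, from 9234451 to 17638156 at 18 months. That library, replicate 3 of the 18-month female controls, had 403108 counts and 10027 genes detected, against 11382 to 14718 genes in the other libraries. It is called the low-total control here. Over the 170 pairs of replicates, Pearson's r of log CPM across genes ran from 0.856 to 0.988. The summed CPM of 4 Y-linked genes was 43.4 or more in every male but replicate 5 of the 9-month 5 mg/kg group, which had 13.4. It was 1.46 or less in every female but the low-total control, which had 22.3.

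Each dose was compared with 0 mg/kg within a sex and duration, to ask which liver transcripts responded to it. Changes are log2 fold changes ± SE of the fit, and levels are CPM ± SD with n animals. Ppara encodes the nuclear receptor PPAR-alpha, which switches on genes of fatty acid oxidation. Its own transcript was not called changed at any dose, and its log2 change at 5 mg/kg was 0.03, 0.2, -0.42 and 0.1 in 9-month males, 9-month females, 18-month males and 18-month females.

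At 5 mg/kg for 9 months, 729 genes rose and 708 fell of 11371 tested in male liver. The 8 largest rises in genes with a mean of at least 10 raw counts per library in both groups were in genes of fatty acid breakdown, binding or uptake, while some genes with fewer counts rose by more. Ehhadh, the bifunctional enzyme of peroxisomal beta-oxidation, rose from 418 ± 111 CPM (n = 4) to 14200 ± 5160 (n = 5), by 5.09 ± 0.33 (adjusted p = 5.61e-11). Cyp4a14 and Cyp4a10, which hydroxylate the end of fatty acid chains, rose by 6.2 ± 0.67 and 5.58 ± 0.6. Acot2 and Acot1, which split acyl-CoA, rose by 5.96 ± 0.4 and 4.87 ± 0.41, and Cpt1b, which carries fatty acids into mitochondria, by 5.06 ± 0.44. Fabp4, a fatty acid binding protein, rose from 17.3 ± 9.77 to 1290 ± 1040 CPM, and Cd36, a fatty acid transporter, from 7.06 ± 2.15 to 196 ± 101. Of 20 peroxisomal beta-oxidation genes tested, 12 rose and 2 fell (16 and 3 adjusted over the list alone), with a camera adjusted p of 1.69e-15. The 2 falls were Scp2 by -0.74 and Nudt7 by -1.21, both chosen after their values were seen. Of 21 mitochondrial oxidation and ketogenesis genes, 16 rose and 0 fell (19 and 0 adjusted over the list alone, camera adjusted p = 2.29e-19), among them Hadhb by 1.76 and Eci1 by 1.58. Of 12 genes of omega-oxidation and thioesterases, 7 rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 1.32e-14). The fall was Cyp4f14 by -2.94, chosen after its values were seen. Of 21 genes of lipid uptake, droplets and secreted PPAR-alpha targets, 15 rose and 0 fell (15 and 0 adjusted over the list alone, camera adjusted p = 4.68e-21). They included the droplet coat gene Plin2 at 2.42 ± 0.27 and the secreted hormone gene Fgf21 at 4.59 ± 0.72. Of 16 fatty acid synthesis genes, 10 rose and 1 fell (11 and 1 adjusted over the list alone, camera adjusted p = 1.74e-08). The desaturase genes Scd1 and Scd2 rose by 2.53 ± 0.3 and 4.14 ± 0.48, and Mlxipl, chosen after its values were seen, fell by 0.61. These 5 list calls held with an estimated correlation, at adjusted p = 0.00121 to 0.0198.

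Genes that break down amino acids and make urea fell in the same livers. Of 20 tested, 16 fell and 0 rose (18 and 0 adjusted over the list alone), with a camera adjusted p of 2.47e-22, which held at adjusted p = 0.0182 with an estimated correlation. Asl and Ass1, of the urea cycle, fell by 1.89 ± 0.22 and 2 ± 0.3, and Prodh, which starts proline breakdown, by 2.46. Male-biased liver genes fell in 9 of 15 and rose in 0 (11 and 0 adjusted over the list alone, camera adjusted p = 8.55e-10, with an estimated correlation adjusted p = 0.0198). Cyp4a12a, a male-biased member of that list, had a log2 change of 0.12 (adjusted p = 0.839). Of 15 glucose metabolism genes, 4 fell and 0 rose (5 and 0 adjusted over the list alone, camera adjusted p = 8e-06, with an estimated correlation adjusted p = 0.0213), with the fructose kinase gene Khk at -1.41, Pklr at -1.62 and Pygl at -0.83 among the falls. Large falls among all genes, kept without each library in turn, included Gm10681 by 6.12 ± 0.42, the steroid dehydrogenase gene Hsd3b2 from 339 ± 73.8 to 14.6 ± 10.9 CPM, and Cyp2c54 from 2030 ± 488 to 104 ± 97.1. Serpina4-ps1, the largest fall at -7.15 ± 1.6, lost its call without 5 mg/kg replicates 4 and 5 (adjusted p = 0.0576), and Ren1, at -4.57, lost its call without several single libraries. Arf1, at -5.28, rested on control replicate 3 and stood at 0.16 without it.

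Lists of the p53 response, stellate cells and matrix, and fetal and tumour markers were called higher. Of 14 p53 and DNA damage genes, 4 rose and 0 fell (7 and 0 adjusted over the list alone, camera adjusted p = 0.000666, with an estimated correlation adjusted p = 0.0229). They were the stress genes Gadd45b at 3.4 ± 0.58, Gadd45a at 1.9, Ccng1 at 0.75 and Phlda3 at 2.58. Of 15 stellate and matrix genes, 6 rose and 0 fell (6 and 0 adjusted over the list alone, camera adjusted p = 0.000666, with an estimated correlation adjusted p = 0.0439), with the collagen gene Col4a1 at 2.8. Of 7 fetal and tumour markers, 5 rose and 0 fell (5 and 0 adjusted over the list alone, camera adjusted p = 0.000149, with an estimated correlation adjusted p = 0.0213). They were Ly6d at 6.74 ± 1.33, Akr1c18 at 6.5 ± 1.49, Scd2, Golm1 at 1.61 and Lgals3 at 3.24, the last chosen after its values were seen. Libraries of this group stood apart in these lists. Replicate 4 had 144 CPM of the fetal protein gene Afp and 48.5 of the pancreatic enzyme gene Cela1, and replicate 5 had 60.3 CPM of Cela1. Without both, an alternative chosen after seeing the data, 799 genes were called, and the calls of Akr1c18 (adjusted p = 0.052), Gadd45a (adjusted p = 0.0982), Ccng1 and Phlda3 were lost. The fetal, stellate and amino acid lists then had camera adjusted p = 9.77e-05, 2.42e-05 and 1.09e-21. No such value is given here for the p53 list, so its call is not shown to hold without these 2 libraries.

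Other lists moved in these males, with calls lost with an estimated correlation. Of 22 cell cycle genes, 5 rose and 0 fell (13 and 0 adjusted over the list alone, camera adjusted p = 3.1e-08, with an estimated correlation adjusted p = 0.0731). They were the cyclin gene Ccnd1 at 4.19 ± 0.57, the replication licensing genes Mcm6 at 3.33, Mcm2 at 1.69 and Mcm3 at 2.16, and Ccna2 at 3.09, the last chosen after its values were seen. Of 27 acute phase and complement genes, 13 fell and 0 rose (15 and 1 adjusted over the list alone, camera adjusted p = 3.77e-11, with an estimated correlation adjusted p = 0.0577), among them the complement gene C9 at -2.67. Of 19 bile acid genes, 6 fell and 0 rose (10 and 1 adjusted over the list alone, camera adjusted p = 5.73e-08, with an estimated correlation adjusted p = 0.0587), with Cyp7b1 at -3.51 ± 0.56. Of 12 periportal hepatocyte genes, 5 fell and 0 rose (8 and 1 adjusted over the list alone, camera adjusted p = 5.8e-07, with an estimated correlation adjusted p = 0.079), with Hal at -1.97 and Gls2 at -1.99. Of 12 pericentral genes, 3 fell and 0 rose (3 and 0 adjusted over the list alone, camera adjusted p = 0.000275, with an estimated correlation adjusted p = 0.167), with Oat at -2.83, Slc1a2 at -3.18 and Cyp1a2 at -1.73. Of 15 targets of the drug receptors CAR and PXR, 4 fell and 0 rose (5 and 1 adjusted over the list alone, camera adjusted p = 0.00421, with an estimated correlation adjusted p = 0.241). That list had a median of 0.02 and a mean of -0.6. Single libraries stood apart in the zonal lists: the periportal list stood at a median log2 difference of -2.14 from the other 4 libraries in replicate 5 (0.53 to 0.72 in the others), and the pericentral list at -2.47 in replicate 4. Without both libraries the 2 lists had camera adjusted p = 9.73e-07 and 0.000787, with 3 and 2 genes called lower. Cyp2b10 and Cyp1a2 lost their calls without replicates 4 and 5 (adjusted p = 0.0594 and 0.0782). Mcm3 and Cyp1a2 also lost theirs without some single libraries.

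The remaining 12 lists were not called in 9-month males at 5 mg/kg. Cholesterol synthesis and uptake had 2 rises of 23, Fdps and Fdft1 (7 and 1 lower adjusted over the list alone, camera adjusted p = 0.1), and AhR targets 2 falls of 7, Cyp1a2 and Ugt1a6a (camera adjusted p = 0.248). Oxidative stress and glutathione had 3 rises of 18, Gpx4, Nfe2l2 and Srxn1, and 2 falls, Gclm and Gsta4 (camera adjusted p = 0.965). ER and amino acid stress had the rise of Atf3 and the fall of Herpud1 among 15 (camera adjusted p = 0.936). Female-biased liver genes had 2 rises of 15, Cyp2b9 and Hao2, and 2 falls, Cyp3a41a and Cyp3a41b. Cyp2b9, a female-biased cytochrome gene, rose by 4.4 ± 0.73, from 2.62 ± 1.59 to 55.3 ± 29.8 CPM. Srxn1, Hao2 and Cyp3a41b were chosen after their values were seen. In this list and in the oxidative stress list camera's direction was lower, while their means were 0.43 and 0.24. Markers of macrophages had 1 rise of 12, Gpnmb, at 9.65, and those of cholangiocytes 2 of 5, Krt23 and Prom1 (camera adjusted p = 0.0688). Endothelial markers had 1 rise of 10, Egfl7, at 0.82. Lymphocytes and plasma cells (camera adjusted p = 0.231), blood cells (camera adjusted p = 0.793) and the sex chromosome genes (camera adjusted p = 0.241) had 0 called genes by edgeR. Of the adipocyte and pancreas list, too few genes for a list test were measured, and Cela1 rose by 4.84, a call lost without replicates 4 and 5 (adjusted p = 0.344). Fdps, Fdft1, Ugt1a6a, Atf3, Herpud1, Cyp3a41a and Prom1 lost their calls without some single libraries, and the count was 1043 to 1402 without each library in turn.

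In 9-month females, 5 mg/kg raised 160 and lowered 82 of 11642 genes (n = 5 in each group). Ehhadh rose by 3.89 ± 0.21 (adjusted p = 3.48e-13), from 515 ± 111 to 7670 ± 2920 CPM, and Retsat, a retinol saturase, by 3.7 ± 0.24, from 72.6 ± 25.6 to 944 ± 314. Cyp4a14, Cyp4a10 and Acot1 rose by 4.3 ± 0.61, 4.04 ± 0.47 and 4.03 ± 0.48. Sult2a7, a sulfotransferase gene, was called at 5.13, which was lost without control replicate 1 or 3 (adjusted p = 0.0599 and 0.0656). Of the peroxisomal list, 10 rose and 0 fell of 20 (18 and 0 adjusted over the list alone, camera adjusted p = 7.79e-47). In the mitochondrial list 14 of 21 rose (18 adjusted over the list alone, camera adjusted p = 1.46e-35), in the omega-oxidation list 8 of 12 with the fall of Cyp4f14 (11 and 1 adjusted over the list alone, camera adjusted p = 1.41e-27), and in the lipid uptake list 12 of 19 (13 adjusted over the list alone, camera adjusted p = 4.46e-27). These 4 calls held with an estimated correlation, at adjusted p = 5.26e-05 to 0.000838.

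Female-biased liver genes fell in 8 of 17 and rose in 0 in these females (9 and 0 adjusted over the list alone, camera adjusted p = 1.57e-14, with an estimated correlation adjusted p = 0.00399). The cytochrome gene Cyp3a41a fell by 2.31 ± 0.38. Sult3a1 fell by 3.64 ± 0.84, a call lost without control replicate 2 or any of 5 mg/kg replicates 1 to 4 (adjusted p = 0.0534 to 0.08). Of 12 male-biased genes, 2 rose and 0 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.00345, with an estimated correlation adjusted p = 0.155). They were Cyp4a12a, from 2.64 ± 1.1 to 32 ± 29.9 CPM, and Elovl3, a fatty acid elongase gene, by 2.16 ± 0.36. Of 16 fatty acid synthesis genes, 3 rose (5 and 1 lower adjusted over the list alone, camera adjusted p = 2.61e-06, with an estimated correlation adjusted p = 0.115), namely Me1 at 1.43, Scd1 at 1.96 and Elovl5 at 1.17. Of 20 amino acid and urea genes, 4 fell (8 adjusted over the list alone, camera adjusted p = 8.11e-06, with an estimated correlation adjusted p = 0.251), namely Asl at -0.72, Ass1 at -0.81, Prodh at -0.94 and Got1 at -1.06, the last chosen after its values were seen. A further 8 lists were called, each with an adjusted p of 0.116 or more with an estimated correlation. Among them were the CAR and PXR targets with the 1 rise of Aldh1a1 by 1.92 and the cell cycle list with 0 calls by edgeR. The count fell to 157 without control replicate 1, 145 without control replicate 3 and 141 without 5 mg/kg replicate 1, and DESeq2 called 458. Scd1 lost its call without control replicate 1, and Elovl5, Asl, Ass1 and Prodh lost theirs without several single libraries.

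After 18 months, 5 mg/kg raised 203 and lowered 73 of 13002 genes in males (n = 3 against 5). Ehhadh rose by 5.52 ± 0.64 (adjusted p = 0.000123), from 402 ± 148 to 18300 ± 8340 CPM, and Acot2 by 6.17 ± 0.47. Pdk4, a kinase that shuts off pyruvate oxidation, rose from 0.775 ± 0.719 to 120 ± 132 CPM (30, 272 and 56.8 in the 3 livers), by 7.31, or 5.83 without replicate 2, Cpt1b by 5.22 ± 0.52 and Cd36 by 4.26 ± 0.54. Of the lipid uptake list, 10 of 21 rose (15 adjusted over the list alone, camera adjusted p = 7.22e-30), which held at adjusted p = 5.12e-06 with an estimated correlation. In the peroxisomal list 7 of 20 rose (10 adjusted over the list alone, camera adjusted p = 7.99e-15), in the mitochondrial list 6 of 21 (13 adjusted over the list alone, camera adjusted p = 2.8e-15), and in the omega-oxidation list 7 of 12 (7 and 1 lower adjusted over the list alone, camera adjusted p = 7.99e-15). With an estimated correlation these 3 had adjusted p = 0.136, 0.136 and 0.101. Abcc4, a transporter that exports bile acids, rose by 3.33 ± 0.41. In the p53 list, Gadd45a and Gadd45b were the 2 rises of 15, calls lost without 5 mg/kg replicates 2 and 3 respectively (camera adjusted p = 0.0166, with an estimated correlation adjusted p = 0.68). Of 15 male-biased genes 0 were called by edgeR, with 9 lower adjusted over the list alone and a camera adjusted p of 3.47e-07, lost at adjusted p = 0.462 with an estimated correlation. Control replicate 5 had 9.02 CPM of Cyp4a12a and 342 of Afp, where the other 4 controls had 307 to 489 and 1.49 to 12.8. The cell cycle list and the amino acid and urea list were also called (camera adjusted p = 0.0166 and 0.00723), with 0 genes called by edgeR and adjusted p = 0.702 and 0.68 with an estimated correlation.

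Single livers decided some calls in these males. Saa1 and Saa2, the acute phase genes of serum amyloid A, were called higher at 6.75 ± 1.4 and 7.18 ± 1.53, but replicate 2 of the 5 mg/kg group had 118000 CPM of Saa1 and replicates 1 and 3 had 337 and 108. Without replicate 2 they stood at -0.71 and -0.61. In 27 acute phase genes, 2 rose and 1, Serpina1a, fell by 3, the last chosen after its values were seen (8 and 5 adjusted over the list alone, camera adjusted p = 0.679). That list had a median of 0.83 and camera's direction was lower. Gm10681 at -6.99, Rdh16f2 at -4.17 and Lama3 at -4.75 lost theirs without 5 mg/kg replicate 2 or 3. The count was 119 to 159 without any of control replicates 1 to 4, 133 and 143 without 5 mg/kg replicates 2 and 3, and 599 with DESeq2.

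In 18-month females, 5 mg/kg raised 134 and lowered 129 of 12421 genes (n = 5 in each group). Ehhadh rose by 3.85 ± 0.51 (adjusted p = 0.000718), from 698 ± 221 to 10100 ± 5510 CPM, Cyp4a14 by 4.3 ± 0.84 and Cyp4a10 by 3.95 ± 0.81. Krt23, a keratin gene, rose by 5.37 ± 0.87, from 0.876 ± 0.68 to 44.5 ± 16.5 CPM. In the peroxisomal list 10 of 20 rose (14 adjusted over the list alone, camera adjusted p = 2.7e-24), in the mitochondrial list 10 of 21 (19 adjusted over the list alone, camera adjusted p = 1.28e-24), in the omega-oxidation list 7 of 12 with the fall of Cyp4f14 (9 and 1 adjusted over the list alone, camera adjusted p = 9.05e-13), and in the lipid uptake list 9 of 20 (15 adjusted over the list alone, camera adjusted p = 1.28e-24). These 4 held with an estimated correlation, at adjusted p = 0.000273 to 0.0252. Me1, Scd1 and Scd2 were the 3 rises of 16 fatty acid synthesis genes (4 adjusted over the list alone, camera adjusted p = 1.91e-07, with an estimated correlation adjusted p = 0.139).

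Falls in these females included Sult3a1, a sulfotransferase gene, from 404 ± 365 to 13.9 ± 16.8 CPM. Female-biased genes fell in 4 of 17 (8 adjusted over the list alone, camera adjusted p = 1.91e-07, with an estimated correlation adjusted p = 0.143). Acute phase and complement genes fell in 6 of 27 (18 adjusted over the list alone, camera adjusted p = 7.87e-15, with an estimated correlation adjusted p = 0.143), with C9 at -2.61, a call lost without some single libraries. Control replicate 4 stood apart in acute phase transcripts, with 41900 CPM of Saa1 against 220 to 2630 in the other controls. Pericentral genes had 1 fall of 12, Slc1a2, by 2.18 ± 0.35 (4 adjusted over the list alone, camera adjusted p = 1.33e-05, with an estimated correlation adjusted p = 0.143), and macrophage markers 1 of 15, Vsig4, by 1.32 and likewise lost without some (11 adjusted over the list alone, camera adjusted p = 4.42e-05, with an estimated correlation adjusted p = 0.308). A further 5 lists were called, each with an adjusted p of 0.143 or more with an estimated correlation. They were oxidative stress and glutathione, higher (camera adjusted p = 0.00203), and 4 that were lower. The lower ones were male-biased genes, stellate cells and matrix, endothelial cells and blood cells (camera adjusted p = 0.034, 0.00294, 0.0183 and 0.034). Results of these lists without the low-total control are not given here, so the part of that library in the calls stays open. The low-total control stood apart from the other controls, with 204 CPM of Cela1 against 5.44 or less. Without it 158 genes were called, with 4 rises in the peroxisomal list, 7 in the mitochondrial list and 5 falls in the acute phase list, while Cyp4a12a was gained at 5.74. Of the 8 largest falls 6, Slc16a3, Rhoj, Gm49368, Tet3, Procr and Adcy3, lost their calls without it (adjusted p = 0.205 to 0.95). The count was also 608 and 444 without control replicates 1 and 5, 103, 103, 88, 168 and 142 without 5 mg/kg replicates 1 to 5, and 727 with DESeq2.

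**Figure D1:**
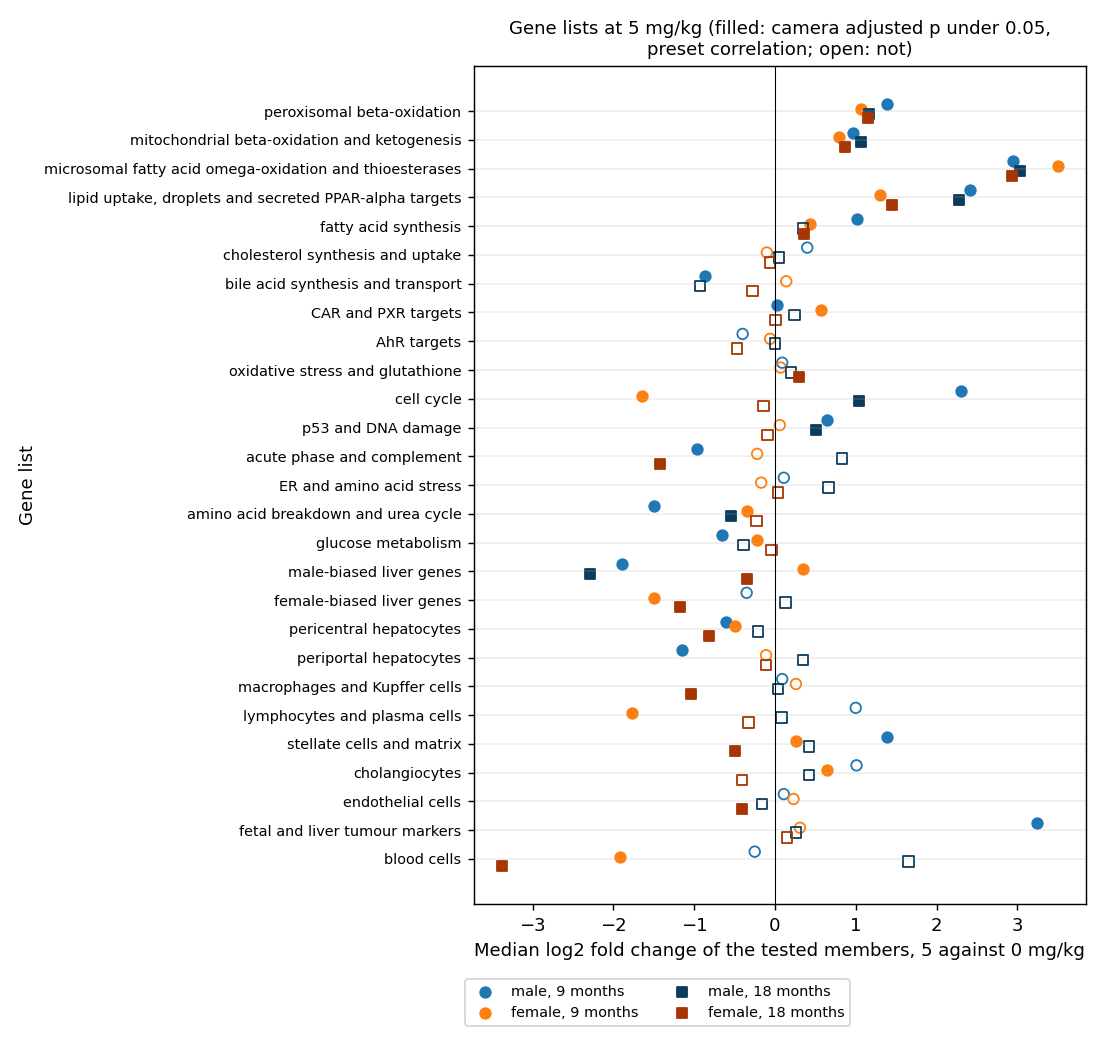
Median log2 change at 5 mg/kg (horizontal axis) of the tested genes of each of 27 gene lists (vertical axis), by sex and duration. Filled symbols mark a camera adjusted p under 0.05, and the peroxisomal, mitochondrial, omega-oxidation and lipid uptake lists lie above 0 in each of the 4 sets.

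At 0.5 mg/kg, genes of fatty acid oxidation rose in males at both durations. In 9-month males (n = 5 against 4) 61 genes rose and 11 fell, and in 18-month males (n = 5 in each group) 27 rose and 0 fell. At 9 months Ehhadh rose by 3.24 ± 0.3 to 3930 ± 1430 CPM (adjusted p = 2.84e-07), Cyp4a14 by 5.53 ± 0.65, Cyp4a10 by 4.79 ± 0.58 and Cd36 by 3.62 ± 0.5. Acot3 was called at 3.28, which was lost without control replicates 1, 3 or 4 or 0.5 mg/kg replicates 1, 2 or 5 (adjusted p = 0.0511 to 0.118). At 18 months Ehhadh rose by 4.34 ± 0.58 to 8170 ± 4570 CPM (adjusted p = 0.00141), Acot3 by 4.61 ± 0.73 and Acot2 by 3.86 ± 0.42. Cyp4a14 at 18 months, at 4.66 ± 0.88, lost its call without control replicates 2, 3 or 4 or 0.5 mg/kg replicates 4 or 5 (adjusted p = 0.0639 to 0.126). In 9-month males the peroxisomal list had 8 rises (15 adjusted over the list alone, camera adjusted p = 9.51e-28), the mitochondrial list 5 (15 adjusted over the list alone, camera adjusted p = 7.89e-25), the omega-oxidation list 6 (7 adjusted over the list alone, camera adjusted p = 2.69e-23) and the lipid uptake list 5 (8 adjusted over the list alone, camera adjusted p = 6.49e-17). These held with an estimated correlation, at adjusted p = 0.00275 to 0.00769, and the other 8 called lists did not (adjusted p = 0.206 to 0.669). In 18-month males the same lists had 3, 1, 6 and 3 rises (9, 11, 7 and 7 adjusted over the list alone), with camera adjusted p = 1.22e-24, 6.98e-20, 4.12e-23 and 3.11e-24. With an estimated correlation they had adjusted p = 0.0234, 0.0675, 0.0203 and 4.31e-05. Of the 10 lists called by camera in these males, the others had adjusted p = 0.719 to 0.822 with it. The falls at 9 months included 2010003K11Rik, by 2.93, and Hsd3b2, to 72 ± 23.5 CPM, a call lost without control replicate 4 or 0.5 mg/kg replicate 5. The 9-month count was 43 and 37 without control replicates 1 and 4, 45 without 0.5 mg/kg replicate 5, and 180 with DESeq2. The 18-month count was 10, 15 and 15 without control replicates 2, 3 and 4, 16 without 0.5 mg/kg replicate 4, and 108 with DESeq2.

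In females at 0.5 mg/kg, 1 gene rose and 0 fell at 9 months, and 0 genes were called by edgeR at 18 months. The rise was Retsat, from 72.6 ± 25.6 to 187 ± 29.2 CPM (n = 5 in each group), at 1.36 ± 0.22 (adjusted p = 0.0168). That call was lost without control replicate 2 (adjusted p = 0.132) or 0.5 mg/kg replicates 3 or 5 (adjusted p = 0.0589 and 0.107), and 3 genes were called without 0.5 mg/kg replicate 1. Ehhadh stood at 898 ± 81.1 CPM at 9 months and 1780 ± 1050 at 18 months. The unadjusted p was under 0.05 in 1054 genes at 9 months and 1033 at 18 months, and DESeq2 called 96 and 36 genes. Both unadjusted counts exceed a share of 0.05 of the genes tested, which chance alone would give, and the excess was not tested. At 18 months 1 gene was called without control replicate 4 and 2 without 0.5 mg/kg replicate 1. The 4 fatty acid and lipid lists were called by camera at both durations, at adjusted p = 1.51e-11, 1.04e-07, 8.78e-09 and 1.51e-06 at 9 months and 4.32e-06, 5.24e-07, 1.66e-05 and 1.67e-06 at 18 months. All 8 calls were lost with an estimated correlation, at adjusted p = 0.0839 to 0.268 and 0.123 to 0.437. At 9 months 8 further lists were called, among them lymphocytes and plasma cells, cell cycle and blood cells with lower values (camera adjusted p = 2.36e-08, 1.22e-06 and 0.000405), and at 18 months blood cells lower (camera adjusted p = 0.0149). These too were lost with an estimated correlation (adjusted p = 0.268 to 0.512, and 0.705). The 18-month value for blood cells includes the low-total control. Adjusted over the list alone, 4 peroxisomal and 5 omega-oxidation genes rose at 9 months.

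**Figure D2:**
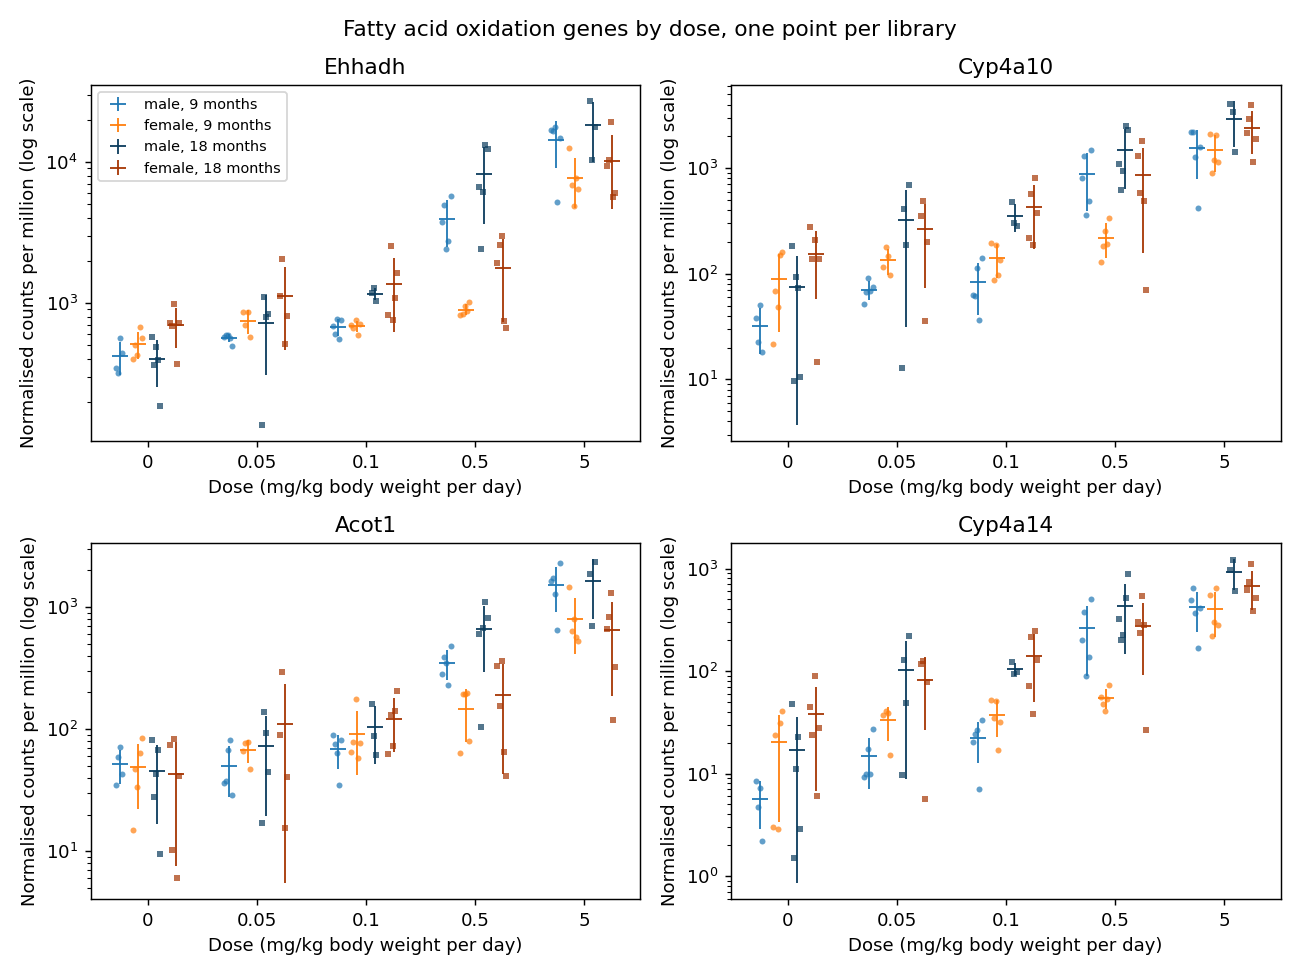
Level in CPM (log axis) of genes of fatty acid oxidation against dose in mg/kg a day, 1 point per animal, with bars for the group mean ± SD. Mean Ehhadh reached 3930 and 8170 CPM in 9- and 18-month males at 0.5 mg/kg, against 898 and 1780 in females, and a lower bar that would pass below 5% of the mean ends there.

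At 0.1 and 0.05 mg/kg few genes were called. In males Stip1, a co-chaperone gene, fell by 2.26 ± 0.34 and Gabpb2, a transcription factor subunit gene, by 1.45 ± 0.22 at 0.1 mg/kg and 9 months (n = 5 against 4, adjusted p = 0.00231 for each). At 0.05 mg/kg for 9 months the 1 call was Cox6b2, chosen after its values were seen, which was lost without control replicates 1, 3 or 4, with 2 genes called without 0.05 mg/kg replicate 4. In 9-month females at 0.1 mg/kg, Gabpb2 fell from 73.9 ± 11.1 to 28.6 ± 8.64 CPM (adjusted p = 0.0436), a call lost without any of replicates 1 to 4 of either group. In 18-month females at 0.1 mg/kg 2 genes were called, among them Wdr46, which fell from 47.7 ± 11.4 to 10.5 ± 2.36 CPM (adjusted p = 0.0348), with 0 or 1 call left without each of the 10 libraries in turn. By edgeR 0 genes were called in 18-month males at 0.1 and 0.05 mg/kg, in 9-month females at 0.05 mg/kg and in 18-month females at 0.05 mg/kg. In those 4 comparisons 397, 1124, 248 and 1115 genes had an unadjusted p under 0.05, and DESeq2 called 11, 19, 0 and 25. Chance alone would give a share of about 0.05 of the genes tested. The counts of 397 and 248 lie below that share and those of 1124 and 1115 above it, an excess that was not tested. Ehhadh stood at 675 ± 95 CPM in 9-month males and 1160 ± 118 in 18-month males at 0.1 mg/kg, and at 688 ± 60 and 1360 ± 736 in females. The peroxisomal list was called higher at 0.1 mg/kg in all 4 sets (camera adjusted p = 0.000445, 1.24e-06, 6.78e-05 and 2.42e-06), and at 0.05 mg/kg in females (0.00254 at each duration). All 6 calls were lost with an estimated correlation, at adjusted p = 0.349 to 0.954. Unrelated lists were called there too. In 9-month females, cell cycle and lymphocytes and plasma cells were lower at 0.1 mg/kg (camera adjusted p = 5.89e-08 each). Amino acid and urea genes were lower at 0.05 mg/kg (camera adjusted p = 1.58e-07). In 9-month males at 0.05 mg/kg, lymphocytes and plasma cells were higher (camera adjusted p = 5.97e-05), and the peroxisomal list had 0.303. With an estimated correlation these lists had adjusted p = 0.279 to 0.822.

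**Figure D3:**
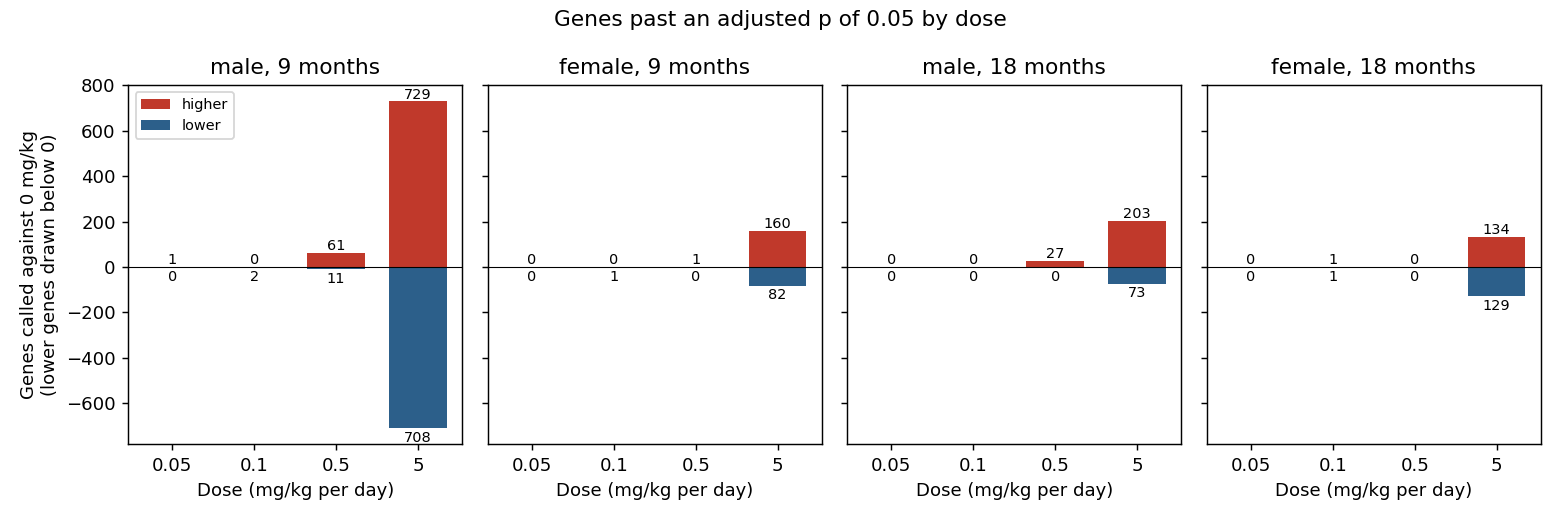
Number of genes called higher and lower (bars, adjusted p under 0.05) at each dose in mg/kg a day, by sex and duration. Calls were most numerous at 5 mg/kg, from 242 in 9-month females to 1437 in 9-month males, and at 0.1 and 0.05 mg/kg no set had more than 2.

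A score of fatty acid oxidation was compared with the controls by a two-sided exact permutation test at each dose. At 5 mg/kg it was 1.58 ± 0.39 and 1.7 ± 0.34 in 9- and 18-month males and 1.41 ± 0.18 and 1.35 ± 0.38 in females (mean ± SD, n = 3 to 5). The exact p was 0.00794 in 3 of these sets and 0.0179 in 18-month males, the smallest that their sizes allow. It was 1.11 ± 0.33 and 1.39 ± 0.4 in males at 0.5 mg/kg (exact p = 0.00794 each) and 0.47 ± 0.2 and 0.46 ± 0.56 in females (exact p = 0.0476 and 0.167). At 0.1 mg/kg it was 0.29 ± 0.13 and 0.65 ± 0.16 in males and 0.28 ± 0.09 and 0.49 ± 0.14 in females, with exact p = 0.0238, 0.0714, 0.167 and 0.0238, and 0.0952 or more when adjusted over the 8 tests at the 2 low doses. At 0.05 mg/kg it was 0.1, 0.01, 0.2 and 0.25, with exact p = 0.389 or more.

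**Figure D4:**
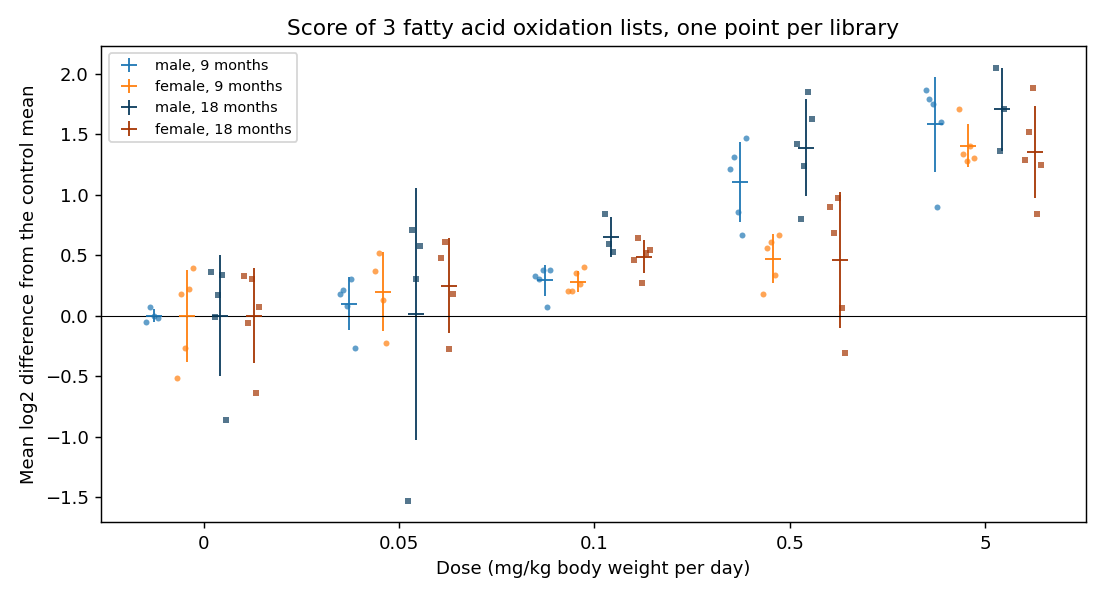
Fatty acid oxidation score (mean log2 difference from the controls of the same sex and duration) against dose in mg/kg a day, 1 point per animal with the group mean ± SD. Group means at 0.5 mg/kg were 1.11 and 1.39 in males and 0.47 and 0.46 in females.

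Whether the sexes responded differently was tested as an interaction. At 0.5 mg/kg and 18 months Ehhadh responded less in females, at -3 ± 0.54 (adjusted p = 0.00251), a call kept without each library in turn. At 9 months the difference was -2.43 ± 0.56 (adjusted p = 0.0429), lost without most single libraries (adjusted p = 0.0514 to 0.121). In all, 4 genes responded higher and 35 lower in females at 9 months, and 2 and 50 at 18 months. The 4 were Tuba1c, Stip1, Lysmd3 and Klhl35, the last chosen after its values were seen, and the 2 included Ly6k, and each of the 4 named here within the naming rule lost its call without 1 or more single libraries. The largest of the 35 within the naming rule were not fatty acid genes but the immunoglobulin genes Ighv1-9 and Ighv1-18 and the immune genes Pla2g2d and Cr2, at -14.68, -10.52, -12.04 and -11.53. Cr2 stood at 115 ± 153 CPM in control females and 1.84 ± 1.07 at 0.5 mg/kg, and all 4 lost their calls without any male control. At 18 months the peroxisomal, omega-oxidation, lipid uptake and mitochondrial lists responded lower in females by camera (adjusted p = 3.4e-09, 4.59e-07, 2.81e-05 and 1.14e-05), with adjusted p = 0.173 to 0.551 with an estimated correlation. At 9 months the peroxisomal list had adjusted p = 0.00319, and 0.694 with an estimated correlation. The 9-month count was 14, 1, 0 and 2 without male controls 1 to 4, 5 and 4 without female controls 1 and 3, 5 without male 0.5 mg/kg replicate 4, and 10 to 14 without any female 0.5 mg/kg replicate. The 18-month count was 2 without the low-total control and 192 to 206 without any other female control. It was 4 to 15 without any male control, 29, 18 and 7 without male 0.5 mg/kg replicates 1, 3 and 5, and 3 to 12 without female 0.5 mg/kg replicates 2 to 5. Among the largest differences at 18 months, Gm10409, Gabrd and Coch read 0 CPM in females at 0.5 mg/kg, and lost their calls without the low-total control.

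At 5 mg/kg and 9 months, 15 genes responded higher and 20 lower in females than in males. The largest differences within the naming rule were lower in females, with Diaph3, F2rl3 and Exo1 at -12.52, -12.27 and -10.64, each lost without several single libraries, and Sybu at -9.12 ± 1.92 (adjusted p = 0.00886), kept without each library in turn. Levels were low: treated and control females had 0.158 and 2.9 CPM of Diaph3, 0 and 5.14 of F2rl3, and 1.76 and 5.29 of Exo1. The sizes of these differences are therefore uncertain. Sybu stood at 7.08 ± 1.5 CPM in treated and 10.3 ± 4.88 in control females, so little of its difference came from females. The largest difference in which females responded higher was Shh at 7.84, near the detection limit at 1.62 ± 1.5 CPM in treated females, and lost without female control replicate 3 or male 5 mg/kg replicate 5. Elovl3 differed by 5.75 ± 1.15 (adjusted p = 0.00581), standing at 89 ± 40.2 CPM in treated and 19.7 ± 7.1 in control females, while it fell by 3.57 in males. Male-biased liver genes responded higher in females (camera adjusted p = 4.2e-13, and 0.0182 with an estimated correlation). Female-biased, cell cycle, amino acid and urea, bile acid and periportal lists also differed by camera (adjusted p = 4.39e-05, 5.7e-13, 1.31e-12, 8.42e-09 and 3.82e-06), each with adjusted p = 0.11 with an estimated correlation. The count was 22 and 20 without male control replicate 4 and female control replicate 3, 57 without female control replicate 4, and 21 and 23 without male replicate 5 and female replicate 3 at 5 mg/kg. At 18 months 67 responded higher and 365 lower in females. Cyp4a12a differed by 4.68 ± 1.17 (adjusted p = 0.0148; 0.0637 by DESeq2), and Pdk4 by -4.79 ± 1.18 (adjusted p = 0.0129). Both calls were lost without male 5 mg/kg replicate 2 (adjusted p = 0.0847 and 0.253). The female-biased list was called (camera adjusted p = 1.18e-08, and 0.0503 with an estimated correlation). The count was 148 without the low-total control, 736 and 668 without female controls 1 and 5, 268 and 262 without male controls 1 and 2, 718 and 22 without male 5 mg/kg replicates 1 and 2, and 267 and 275 without female 5 mg/kg replicates 1 and 4.

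Responses at 18 months were compared with those at 9 months in the same way. In males at 5 mg/kg 27 genes responded higher and 2, Pnpla5 and Rdh16f2, lower, with Saa1 and Saa2 at 8.15 and 8.28. Without 18-month 5 mg/kg replicate 2 the count was 1. It was 18 and 8 without 9-month control 2 and 18-month control 5, 19 without 9-month 5 mg/kg replicate 4, and 91 and 70 without 18-month replicates 1 and 3. In females at 5 mg/kg 2 genes responded higher and 35 lower. The 2 were Gabpb2, at 2.25 ± 0.32 (adjusted p = 5.08e-06), and Cdadc1, which lost its call without the low-total control. The count was 2 without that library, 173 to 200 without any other 18-month control, 5 to 9 without any 9-month control, 22 without 9-month 5 mg/kg replicate 1 or 2, and 5 to 24 without any 18-month 5 mg/kg replicate. The acute phase list responded higher in 18-month males and lower in 18-month females (camera adjusted p = 7.07e-08 and 9.74e-11), lost at adjusted p = 0.357 and 0.505 with an estimated correlation. At 0.5 mg/kg 2 genes responded higher and 1 lower in males, namely Fam43a at 3.18 ± 0.45, Gabpb2 at 2.24 and Gm4788, the last lost without several single libraries. In females 2 responded higher, among them Gabpb2 at 2.35, and 6 lower. That count was 1 without the low-total control or 18-month 0.5 mg/kg replicate 4, and 109 to 151 without any other 18-month female control. It was 3 or 4 without 9-month controls 1 to 4, 5 without 9-month 0.5 mg/kg replicate 3, and 5 and 3 without 18-month 0.5 mg/kg replicates 2 and 3.

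Calls at 5 mg/kg overlapped between sexes and durations, which share no library. Males and females shared 112 rises at 9 months, where 10.2 were expected if calls fell independently among the genes tested in both, and 45 at 18 months, where 2.15 were expected (Fisher's exact p = 2.13e-98 and 2.63e-48). The 2 durations shared 128 rises in males, with 12.2 expected, and 63 in females, with 1.83 expected (Fisher's exact p = 2e-108 and 1.27e-85). Shared falls numbered 36 and 14 between the sexes, with 4.75 and 0.741 expected, and 48 and 19 between the durations, with 4.48 and 0.869 expected (Fisher's exact p = 1.09e-23, 1.29e-14, 5.42e-41 and 7.8e-21). These p-values treat genes as independent draws, which genes that move together are not, and do not measure the spread between animals. In all 4 sets 35 genes rose, among them Ehhadh, Acot1, Acot2, Cpt1b, Cd36, Cyp4a10, Cyp4a14, Plin2 and Retsat, and 1 fell, the organic anion transporter gene Slc22a7. Slc22a7 lost its call in 18-month males without any 5 mg/kg library.

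Control livers were compared to show the sex and age differences without treatment. At 9 months 118 genes were higher and 113 lower in females than in males (n = 5 against 4). Sult2a1, a sulfotransferase gene, was higher by 7.01 ± 0.87, at 4280 ± 1140 against 33.3 ± 6.44 CPM, and Cyp4a12a lower by -6.13 ± 0.83, at 2.64 ± 1.1 against 184 ± 30.2. Female-biased, male-biased and sex chromosome lists were called (camera adjusted p = 6.97e-42, 1.21e-32 and 1.15e-32) and held with an estimated correlation, at adjusted p = 9.91e-09, 3.64e-06 and 1.17e-12. At 18 months 1060 were higher and 320 lower (n = 5 in each group), with Cyp4a12a at -6.27, and 421 genes were called without the low-total control. The 9-month count was 148, 144 and 151 without male controls 1, 3 and 4, and 133 and 131 without female controls 1 and 3. Between 9 and 18 months 41 genes were higher and 32 lower in males, and 1243 and 324 in females. Fam43a and Gabpb2 were lower in 18-month males by -2.86 ± 0.34 and -1.76 ± 0.23 (adjusted p = 2.2e-08 and 3.09e-07). Slpi, Fabp5, Il1rn and Tmem86a were called higher there and lost the call without control replicate 5. The male count was 19, 19, 12 and 14 without 9-month controls 1 to 4 and 120, 48 and 4 without 18-month controls 2, 4 and 5. In 18-month females Lcn2, an acute phase gene, was higher by 4.94 ± 1.37, at 1000 ± 1180 against 32.9 ± 29.4 CPM, and 986 genes were called without the low-total control. Gata1 and Zmiz1, at 5.9 and 4.51, turned to -1.32 and -0.2 without it. In females the acute phase list was called higher (camera adjusted p = 1.19e-19, and 0.184 with an estimated correlation). Single 18-month livers stood apart in these genes, with 2600 and 1930 CPM of Lcn2 in replicates 4 and 2 against 29.1 to 296 in the others, and Lcn2 stood at 4.21 without replicate 4.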

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

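The test for male liver in the low-total control and the 3 tests of the male library low in Y-linked transcripts were chosen after the results were seen, and the others before.

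Replicate 3 of the 18-month female controls held 403108 counts, 22.3 CPM of Y-linked transcripts and 204 CPM of Cela1, a pancreatic enzyme gene. It detected 10027 genes, while the other 4 controls, thinned to its total, detected 9434 to 9945. That does not decide against low depth alone. Each control was thinned once, and the controls spread further among themselves than the highest of them lies below this library. Genes under 1 CPM in each of the other 91 libraries took 0.633% of its counts, against a median of 0.0063% and at most 0.0302% elsewhere, as counts spread over probes of genes that liver does not express would give. Male liver in the library also stays open: 8 male-biased genes stood at a median of 14.7% of the male control level (3.36 to 473%), and the 4 Y-linked genes at 28.3%. Few counts bear on this: the library held 6 of Ddx3y, 1 each of Uty and Kdm5d and 0 of Eif2s3y. The male-biased genes used held from 6 counts (Cyp7b1) to 535 (Gstp1). Each of these explanations is technical, as male liver would be another sample mixed in, and no biological explanation was tested.

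Replicate 5 of the 9-month males at 5 mg/kg had 13.4 CPM of Y-linked transcripts. Counting noise is argued against, since it held 70 counts of Ddx3y where 354 were expected (95% interval 318 to 391), and its 11.3 CPM lay below the 33.5 to 74.9 of the other 43 males. Female liver mixed in is argued against, since 8 female-biased genes showed a median of -1.75% of the rise that a missing Y-linked share of 80.2% would need, and at most -0.233%. A hypothesis that stays open is a mass of liver cells that lost the Y chromosome and held few resident macrophages: its macrophage list stood at a median log2 difference of -0.51 from the other 4 libraries, the lowest of the 5. That low value is not particular to macrophages, since the endothelial and cholangiocyte lists were also lowest there, at -0.58 and -0.59. No tissue description in the labels bears on this, so it may be wrong.

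At 0.5 mg/kg fatty acid oxidation genes had larger estimated rises in males than in females. The list differences called by camera were lost with an estimated correlation (adjusted p = 0.173 to 0.551 at 18 months and 0.694 at 9 months), and Ehhadh's difference at 9 months was lost without most single libraries. At 18 months Ehhadh differed by -3 ± 0.54 (adjusted p = 0.00251), a call kept without each library of the groups compared in turn. The splits below leave chance open for the number of genes over all genes tested, which is not a test of these lists. A few mislabelled male libraries are argued against, since 10 of 10 male libraries at 0.5 mg/kg had a score above every male control of their duration. Different depth was examined by thinning 91 libraries to 4443349 counts. Of the median sex difference, 94.5% was kept at 18 months (-1.28 before and -1.21 after), and 102% at 9 months (-1.21 and -1.24). That median is over the 20 genes of these lists called higher at 0.5 mg/kg in males of either duration. This choice favours a larger male response, so the size of the median is not an estimate for the lists. Thinning leaves the expected ratios of CPM unchanged, so the median could hardly have shrunk, and the test does not decide about depth. At 9 months there was also little difference in depth to remove. Median totals at 0 and 0.5 mg/kg were 5364305 and 5501759 counts in males and 5444380 and 5699024 in females. Sex itself, which the design names, remains as a hypothesis that these data cannot test further.

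In 8 comparisons between groups an interaction test called genes. In 6 of them the splits below leave chance open, and in none do they test whether the responses differ. The sex difference at 5 mg/kg covered 35 genes at 9 months and 432 at 18 months, where Pdk4 differed by -4.79. The duration difference at 5 mg/kg covered 29 genes in males and 37 in females. The sex difference at 0.5 mg/kg covered 39 genes at 9 months, with Ehhadh at -2.43, and 52 at 18 months, with Ehhadh at -3. The duration difference at 0.5 mg/kg covered 3 genes in males and 8 in females.

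Single libraries lay far from their group in 20 of 234 group values tested, by the gap to the nearest value over the range of the group. Independent values with a normal spread would give about 1 in 20, or 11.7. CPM of genes that move together in the same animals are not such values, so 11.7 is a rough guide only. Groups of 3 animals were not tested. Replicate 1 of the 18-month male controls had 9.23 M counts (9234451), with 15.5 M (15543185) the nearest. The fatty acid oxidation score was low in replicate 4 of 9-month males at 0.1 mg/kg (0.07, nearest 0.3) and at 5 mg/kg (0.9, nearest 1.6), and high in replicate 1 of 9-month females at 5 mg/kg (1.71, nearest 1.4). That female library also had the highest Acot1 at 1470 CPM (nearest 801), and replicate 4 of those males had the lowest Ehhadh at 5210 CPM (nearest 14700). Replicate 4 of 9-month females at 0.05 mg/kg was lowest in Cyp4a14 at 15.1 CPM (nearest 37.4). Acot1 stood at 177 CPM in replicate 3 of 9-month females at 0.1 mg/kg (nearest 78.4), and Ehhadh at 498 CPM in replicate 5 of 9-month males at 0.05 mg/kg (nearest 568). Pdk4 was high in replicate 4 of 18-month males at 0.5 mg/kg (22.5 CPM, nearest 7.06), replicate 5 of 9-month males at 5 mg/kg (62, nearest 27.5) and replicate 3 of 18-month females at 5 mg/kg (34.4, nearest 12.1). Fgf21 was high in replicate 5 of the 18-month male controls (21.4 CPM, nearest 4.21), replicate 1 of 9-month males at 0.1 mg/kg (5.01, nearest 1.19), replicate 2 of 18-month males at 0.5 mg/kg (45.8, nearest 12), replicate 4 of 9-month females at 0.5 mg/kg (4.73, nearest 1.57) and replicate 4 of 18-month females at 5 mg/kg (33.7, nearest 9.6). Cyp3a11 was high in replicate 4 of 18-month females at 0.05 mg/kg (1640 CPM, nearest 634) and of 9-month females at 5 mg/kg (756, nearest 401), and Ppara in replicate 4 of the 18-month male controls (218 CPM, nearest 151).

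Other splits of the same animals into groups of the same sizes were fitted to ask whether chance can be excluded. At 5 mg/kg it can in each set: the real count came up in 1 of 100 splits in 9-month males (1437 genes, highest other 763) and 9-month females (242, highest other 29), 1 of 56 in 18-month males (276, highest other 12) and 1 of 100 in 18-month females (263, highest other 8). It can at 0.5 mg/kg in 1 of 100 splits for 9-month males (72, highest other 28) and 18-month males (27, highest other 1). In sets with 1 or 2 calls the share was below the one set beforehand, but chance is not called excluded, given the limits below. At 0.5 mg/kg this was 9-month females (3 of 100, 1 gene, highest other 1). At 0.1 mg/kg it was 9-month males (2 of 100, 2, highest other 13), 9-month females (3 of 100, 1, highest other 1) and 18-month females (3 of 100, 2, highest other 78). At 0.05 mg/kg it was 9-month males (3 of 100, 1, highest other 2). Where 0 genes were called, every split reaches the real count. Shares of 100 of 100 or 56 of 56 were then fixed in advance, and the splits cannot decide about chance. That held in 18-month females at 0.5 mg/kg (highest other 415) and 18-month males at 0.1 mg/kg (highest other 0). At 0.05 mg/kg it held in 9-month females (highest other 1400), 18-month males (highest other 371) and 18-month females (highest other 501). The 9-month calls at 0.1 mg/kg were Gabpb2 in females and Gabpb2 and Stip1 in males. Gabpb2 took 2 levels that did not follow dose alike at both durations, and the female call was lost without any of 8 single libraries, so its calls do not show a response to dose. The call of Stip1 in males was kept without each library in turn. The shares of splits were not adjusted over the 16 comparisons, and other counts of 1 or 2 genes changed with the setting: the 0.5 mg/kg count in 9-month females was 0 with only the 2 groups in the fit and its gene was not called with all 92 samples in 1 fit, the 0.05 mg/kg count in 9-month males was 0 with probes not summed, with only the 2 groups and with all 92 samples in 1 fit, and the 0.1 mg/kg count in 18-month females was 0 or 1 without each library in turn. The 1400, 371, 415, 501 and 78 genes of other splits, and the 13 in 9-month males at 0.1 mg/kg, came from groupings that do not follow dose. What set those animals apart was not tested.

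For differences between responses, labels of dose and control were exchanged among the animals of each sex and duration in 25 splits. That removes the dose response itself, so these splits do not test whether 2 groups respond alike. The real count was above every other split for the sex difference at 5 mg/kg and 18 months (1 of 25 splits, 432 genes, highest other 213). That count was 148 without the low-total control and 22 without male 5 mg/kg replicate 2. It was also above every other split for the duration difference at 0.5 mg/kg in males (1 of 25, 3 genes, highest other 2). A share of 1 of 25 is the smallest possible here. Of those 3 genes, Fam43a and Gabpb2 already differed between 18- and 9-month male controls, by -2.86 and -1.76. The third, Gm4788, was lost without several single libraries. Chance cannot be excluded for the sex difference at 5 mg/kg and 9 months (3 of 25, 35 genes, highest other 53), nor at 0.5 mg/kg at 9 months (2 of 25, 39, highest other 45) and 18 months (9 of 25, 52, highest other 146). It cannot be for the duration difference at 5 mg/kg in males (3 of 25, 29, highest other 415) and females (11 of 25, 37, highest other 282), nor at 0.5 mg/kg in females (20 of 25, 8, highest other 313). Splits that gave 146, 415, 282 and 313 genes passed the real counts several times over. Whether single livers or a wider structure of the samples gave them was not tested. Among controls, with sex or age labels exchanged, the real count was above every other split in each comparison (1 of 25). These were sex at 9 months (231, highest other 20) and 18 months (1380, highest other 904), and age in males (73, highest other 25) and females (1567, highest other 1047). Without the low-total control the counts were 421 for sex at 18 months and 986 for age in females. Without 18-month male control replicate 5 the count for age in males was 4. No splits were drawn without these libraries. Chance is therefore called excluded only for sex at 9 months, where 131 or more genes stayed called without each library compared.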

How the results depend on the processing

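The alternative without replicates 4 and 5 of the 9-month males at 5 mg/kg, and the list tests without the low-total control, were chosen after seeing the data; all other alternatives were planned. No paired analysis was possible because replicate numbers were given in accession order and only name samples. With RLE normalisation every list call at 5 and 0.5 mg/kg and every named call at 5 mg/kg kept its direction and its side of the threshold. List calls kept with an estimated correlation were 11 of 17, 5 of 16, 1 of 8 and 4 of 14 at 5 mg/kg (9-month males, 9-month females, 18-month males, 18-month females) and 4 of 12, 0 of 12, 3 of 10 and 0 of 5 at 0.5 mg/kg. With fry they were 17, 10, 4 and 9, and 4, 0, 4 and 0. Named calls kept without each library in turn were 70 of 86, 32 of 45, 17 of 34 and 17 of 30 at 5 mg/kg. Counts below are those that moved by over 1.5 times, and the cause was not tested except where fewer samples are the construction.

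With DESeq2 the counts at 5 mg/kg were 458 in 9-month females, 599 in 18-month males (365 higher) and 727 in 18-month females (245 higher). They were, at 0.5 mg/kg, 180 in 9-month males, 96 in 9-month females (14 higher), 108 in 18-month males (84 higher) and 36 in 18-month females. At 0.1 mg/kg they were 13, 51, 11 and 175 in the same order (8, 9, 4 and 21 higher), and at 0.05 mg/kg 5 in 9-month males, 19 in 18-month males and 25 in 18-month females. The sex difference at 5 mg/kg then covered 231 genes at 9 months (68 higher) and 813 at 18 months, and at 0.5 mg/kg 217 and 303. The duration difference covered 87 genes in males (57 higher) and 231 in females at 5 mg/kg, and 15 (6 higher) and 141 (19 higher) at 0.5 mg/kg. Control comparisons gave 580 for sex at 9 months (400 higher) and 311 for age in males. With all 92 samples in 1 fit, the 9-month male counts were 33, 5 and 0 at 0.5, 0.1 and 0.05 mg/kg, and 4 genes were called in 9-month females at 0.5 mg/kg. In 18-month males they were 776, 82, 4 and 152 from 5 to 0.05 mg/kg (485, 69, 3 and 142 higher), and in 18-month females 1032, 437, 612 and 245, mostly falls (225, 14, 38 and 2 higher). With only the 2 groups in the fit, 9-month males had 9 and 0 at 0.1 and 0.05 mg/kg, 9-month females 136, 0 and 2 at 5, 0.5 and 0.1 mg/kg, 18-month males 109, 44 and 5, and 18-month females 103 at 5 and 1 at 0.1 mg/kg. Without the low-count filter, counts were 3 in 9-month females at 0.5 mg/kg, 123 and 1 in 18-month females at 5 and 0.5 mg/kg, 9 and 15 for the sex difference at 0.5 mg/kg, and 18 for age in males. With probes not summed they were 1 and 0 in 9-month males at 0.1 and 0.05 mg/kg, 2 in 18-month females at 0.5 mg/kg and 21 for the sex difference at 0.5 mg/kg and 9 months. With RLE normalisation they were 77 and 19 for the duration difference in females at 5 and 0.5 mg/kg, 17 and 96 for the sex difference at 0.5 mg/kg, and 118 for age in males.

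Without the low-total control, 158 genes were called in 18-month females at 5 mg/kg and 0 at 0.1 mg/kg. The sex difference at 18 months covered 148 and 2 genes at 5 and 0.5 mg/kg, the duration difference in females 2 and 1, and controls differed in 421 genes by sex at 18 months, 144 by age in males and 986 by age in females. Gata1 and Zmiz1 turned to -1.32 and -0.2 in the last. Without replicates 4 and 5 at 5 mg/kg, 799 genes were called in 9-month males. At an adjusted p under 0.01, shared rises at 5 mg/kg were 60 between sexes at 9 months, 13 at 18 months, 44 between durations in males and 28 in females, and shared falls 11, 0, 4 and 5, since fewer genes pass in each set.

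Without each library of the groups compared in turn, the counts in 9-month males ran from 1043 to 1402 at 5 mg/kg, 37 to 83 at 0.5, 2 to 2 at 0.1 and 0 to 2 at 0.05. They ran from 141 to 238, 0 to 3, 0 to 1 and 0 to 0 in 9-month females, 119 to 314, 10 to 39, 0 to 0 and 0 to 0 in 18-month males, and 88 to 608, 0 to 2, 0 to 1 and 0 to 0 in 18-month females. The sex difference ran from 20 to 57 and 22 to 736 at 5 mg/kg and 0 to 49 and 2 to 206 at 0.5 mg/kg (9 and 18 months). The duration difference ran from 1 to 91 in males and 2 to 200 in females at 5 mg/kg, and 2 to 3 and 1 to 151 at 0.5 mg/kg. Controls ran from 131 to 241 and 421 to 1670 for sex and 4 to 120 and 986 to 1869 for age. Directions turned in Arf1 in 9-month males at 5 mg/kg without control replicate 3 (0.16, and down to -5.69 without another library), in Saa1 and Saa2 in 18-month males without 5 mg/kg replicate 2 (-0.71 and -0.61, and up to 7.33 and 7.84), in Akr1c18 between 18-month controls without male replicate 5 (0.31, and down to -6.6), and in Gata1 and Zmiz1 without the low-total control (-1.32 and -0.2, and up to 6.57 and 4.85). In the simulated data edgeR called 40 of 100 2-fold changes in 9-month males, 3 in 18-month males and 4 for the sex difference at 9 months, so a gene that was not called is not shown to be unchanged.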

Other observations

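The test of a response below 0.5 mg/kg was chosen before its result was seen, and the genes named in this part were chosen after their values were seen, apart from those of the naming rule.

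Single livers at 18 months stood apart from their groups in transcripts of fetal liver and of the acute phase, in treated and control groups alike. Replicate 5 of the 18-month male controls had 342 CPM of Afp and 294 of Gpc3, both genes that fetal liver and liver tumours express, where the other 4 controls had 1.49 to 12.8 and 0.573 to 1.71. The same library had 9.02 CPM of the male-biased Cyp4a12a against 307 to 489, and 1120 of Lcn2 against 7.27 to 51.1. Saa1 reached 118000 CPM in replicate 2 of males at 5 mg/kg, 66400 in replicate 5 of females at 0.5 mg/kg and 41900 in replicate 4 of the female controls, and Lcn2 in those libraries reached 4850, 11400 and 2600.

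Cyp2b9, a female-biased gene, was called higher in 9-month males at 5 mg/kg, and its means in rising order of dose follow. In males they were 2.62, 1.9, 2.67, 19.6 and 55.3 CPM at 9 months (SD 1.59, 0.989, 2.83, 11.9 and 29.8) and 14.9, 5.82, 6.38, 35.1 and 66.1 at 18 months (SD 24.4, 3.57, 4.06, 15.4 and 43.9), where control replicate 5 had 58 CPM and the other 4 had 0.421 to 8.79. In females they were 68, 74.1, 90, 104 and 98.1 CPM at 9 months and 90.2, 115, 111, 117 and 169 at 18 months.

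Gabpb2 took 2 levels that did not follow dose in the same way at both durations. At 9 months it stood at 77.2 and 68.9 CPM in males and 73.9 and 62.9 in females at 0 and 0.05 mg/kg, and at 20.4 to 34.4 from 0.1 mg/kg up. At 18 months it stood at 22.7 to 33 CPM in males at every dose and at 25.8, 27.9 and 30.5 in females up to 0.1 mg/kg, but at 61.5 and 56.2 in females at 0.5 and 5 mg/kg. Replicate 1 of those females at 0.5 mg/kg had 21.7 CPM and replicates 2 to 5 had 67.2 to 76.1. The labels name no batch to set beside these levels.

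A hypothesis of a response below 0.5 mg/kg was tested on the score of fatty acid oxidation, and it can be neither excluded nor called. The two-sided exact p at 0.1 mg/kg was 0.0238 in 9-month males, 0.0714 in 18-month males, 0.167 in 9-month females and 0.0238 in 18-month females, or 0.0952, 0.19, 0.334 and 0.0952 when adjusted over 8 tests. At 0.05 mg/kg it was 0.437, 0.976, 0.444 and 0.389 in the same order.

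Within the 9-month males at 5 mg/kg, the pericentral list stood lowest in replicate 4, at a median log2 difference of -2.47 from the other 4 libraries. The periportal list stood lowest in replicate 5, at -2.14, and the fetal and tumour list highest there, at 1.74. Replicate 4 had 6.4 CPM of the male-biased Cyp2d9, and replicate 5 had 3.5 CPM of the macrophage gene Cd5l.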
